A study of Mus musculus with 9 samples.

How the data were processed

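RNA from liver of male BALB/c mice was purified with a column kit and made into libraries with a SMARTer mRNA kit, per the labels' protocols; no label says whether the kit or the counting used strand, so overlapping and antisense genes cannot be told apart. The 9 libraries fall into the groups CON, CPT and AT3 by their titles, with 3 in each. The authors deposited a table of estimated counts per gene, with gene symbols, lengths and ontology and pathway terms, and a table of TPM values; the aligner and the counting tool are not given in the sources used here. The submitters' processing notes name the builds GRCm38, mm10 and GRCm39 with no role. From 7.96% to 9.55% of all estimated counts in a library, counts of 0 included, were not whole. The deposited estimated counts were therefore rounded before the tests. The authors' TPM values are scaled to gene length and to the same total in each library, and were used here only in alternatives. The group mean columns of the deposited table were not used, and 0 numeric columns of other samples were found. Of the gene identifiers 91.4%, and of tested genes 98.1%, were found in the GENCODE M21 annotation of GRCm38, which gave coordinates and genomic spans.

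The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, its filter on low counts by group, a quasi-likelihood fit of all 9 libraries with 1 term per group, and Benjamini-Hochberg adjustment over 13686 genes, calling genes at adjusted p < 0.05. TMM factors were 0.726 to 0.963 in CON, 1.07 to 1.13 in CPT and 1.05 to 1.13 in AT3. Standard errors of log2 fold changes follow from the quasi-likelihood F statistic. CPM, read counts scaled to a fixed library total, use TMM-scaled library sizes. Gene lists were tested two-sided with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over 51 lists with at least 5 tested members of 55 fixed lists; the other 4 (exocrine pancreas, skeletal muscle, kidney tubule, and gallbladder and mesothelium markers) had 2 or 3 tested members and were not tested. The deposited ontology terms and pathway maps with 15 to 300 tested members, 1293 in all, were tested in the same way. The lists, the tests between groups, the rule for named genes and the alternative settings were set before the data were examined, except the alternatives for annotation terms and the list medians on the TPM scale or without the most abundant genes. Most tests of explanations were set afterwards. The rule takes, per comparison, the 8 largest rises and 8 largest falls among called genes with at least 1 CPM, no overlap of libraries and an ordinary symbol, up to 4 members of each list with the smallest p, 10 genes moved back in AT3 and a fixed set of injury, bile acid, barrier and IL-17 pathway genes. The text prints part of the genes the rule takes, and which of them it prints was chosen after their values were seen; examples for AT3 against CPT were taken mostly from genes whose call held when any library was left out.

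Replicates of each group were compared first: the chi-square statistic per degree of freedom of their counts was 7.71 to 111, so no 2 libraries of a group agreed within sampling noise. Totals were 21485021 to 28480479 counts, and 3 counts correspond to 0.105 to 0.140 CPM. On counts simulated from the CON means with a set of changed genes, the fit recovered 34.3% of genes changed by 1.5-fold, 79.1% at 2-fold and 98.5% at 4-fold for CPT against CON (13093 genes), 41.8%, 82.1% and 98.5% for AT3 against CPT (13083 genes), and 29.9%, 71.6% and 100% for AT3 against CON (13115 genes). In the same simulations 13, 10 and 7 unchanged genes were called. Camera, tested on simulated data with 1 list of 30 genes raised by 1.5-fold, called that list and 0 of 50 unchanged lists in each comparison. Genes were drawn independently of each other there, so this does not show how often lists of correlated genes are called falsely. Alternatives were DESeq2 1.42.0, size factors of DESeq2 in edgeR, no filter on low counts, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), limma-voom with quality weights, only the 6 libraries compared, a minimum log2 fold change of 1, leaving out the mitochondrially encoded and 10 most abundant genes, the replicate number as a block, each library left out in turn, camera with an estimated correlation and fry.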

Results

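Gene expression in liver of male BALB/c mice was measured by RNA sequencing in 9 libraries, 3 from untreated animals (CON), 3 titled CPT and 3 titled AT3. The labels give CPT and AT3 the same treatment, acute liver injury induced by cisplatin, a platinum drug that crosslinks DNA. The abbreviation AT3 is not spelled out there, while the series title names atractylenolide III, a plant sesquiterpene lactone; dose, route and time are not given in the sources used here. The study asks, from its title, whether the compound lessens the liver injury and whether IL-17 signalling through ACT1, TRAF6 and NF-kB takes part. The deposited estimated counts summed to 21485021, 26476936, 24481637 in CON_1 to CON_3, 26584118, 28480479, 23762623 in CPT_1 to CPT_3 and 27459867, 28297486, 26709886 in AT3_1 to AT3_3. Of 57010 genes in the table, 25394 had a count in any library and 13686 passed the filter on low counts and were tested. The labels do not say whether the replicates are separate animals, so p-values measure the spread between these libraries, part of which may be technical.

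Transcripts encoded by the mitochondrial genome took 31.7% ± 5.54 (SD, n = 3) of the counts in CON, 13.5% ± 2.62 in CPT and 10.3% ± 0.944 in AT3. Haemoglobin transcripts took 0.0641% ± 0.00497 in CON, 0.000444% ± 0.000197 in CPT and 0.000633% ± 5.36e-05 in AT3. Albumin took 3.25% ± 0.675, 4.06% ± 0.644 and 5.89% ± 0.0342 in the same order. With 3 libraries a group, a two-sided exact permutation test of these shares cannot go below p = 0.1, which both shares reached in CPT against CON; between AT3 and CPT it gave p = 0.2 for the mitochondrial share and p = 0.3 for haemoglobin. The first principal component of log2 CPM held 76.9% of the variance and parted CON (-101 to -90.7) from the other libraries (35.5 to 53.8). On the next component, with 5.36%, AT3 libraries lay at 18.1 to 20.98, CPT_1 and CPT_2 at -29.5 and -27.8, and CPT_3 at -7.41.

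The comparison of CPT with CON addresses what the cisplatin-injured livers show against untreated ones. Transcripts of secreted acute phase proteins rose, as did those of the metallothioneins Mt1 and Mt2. Lcn2, which encodes a siderophore-binding protein of the acute phase response, measured 3752 ± 161 against 4.86 ± 1.39 CPM (mean ± SD, n = 3 libraries a group), a 782-fold rise with a log2 fold change of 9.61 ± 0.21 (SE) and edgeR adjusted p = 2.28e-14. The metallothionein Mt2, a metal-binding protein, measured 2802 ± 221 against 1.15 ± 0.487 CPM (log2 fold change 11.19 ± 0.22 (SE)), and Saa2, a serum amyloid A, 7491 ± 1612 against 1.91 ± 0.224 CPM (log2 fold change 11.95 ± 0.24 (SE)); Saa1 and Saa2 are near-identical copies, so the division of reads between them is uncertain. Haemoglobin alpha Hba-a2 fell from 338 ± 24.7 to 0.940 ± 0.204 CPM (log2 fold change -8.50 ± 0.17 (SE); reads can be shared with Hba-a1), and the steroid dehydrogenase gene Hsd3b5 from 172 ± 10.1 to 0.974 ± 0.624 CPM (log2 fold change -7.40 ± 0.26 (SE), and -8.08 without CPT replicate 2). The hepcidin gene Hamp2 measured 0.123 ± 0.0569 against 115 ± 30.7 CPM (log2 fold change -9.77).

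Of 13686 tested genes, 8326 were called at edgeR adjusted p < 0.05, 4107 higher and 4219 lower in CPT, and 3960 of them changed by at least 1 on the log2 scale. The 3 CPT and 3 CON libraries did not overlap for 64.2% of the genes, where chance gives 10%. On the TPM scale the median of all genes was higher by 0.29 (log2), and the calls divided into 6631 higher and 1604 lower. In the genome assembly GRCm38 with the GENCODE M21 annotation, matched by gene identifier, Lcn2 (ENSMUSG00000026822) lies on chromosome 2 from 32384633 to 32388252, Saa2 (ENSMUSG00000057465) on chromosome 7 from 46751790 to 46754313, Hba-a2 (ENSMUSG00000069917) on chromosome 11 from 32296489 to 32297298 and Hamp2 (ENSMUSG00000056978) on chromosome 7 from 30922372 to 30924681, all protein-coding.

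Genes with 0 counts in all 3 libraries of a group have only a lower bound, set against 3 counts over the group. The pancreatic elastase gene Cela2a was at least 86.2-fold higher in CPT than in CON and Sec14l5 at least 76.3-fold higher. The long neuronal adhesion gene Ntm was at least 56.2-fold lower and Naaladl2 at least 62.3-fold lower. Immp2l, which encodes a mitochondrial inner membrane peptidase subunit, fell from 37.6 ± 2.92 to 0.207 ± 0.0135 CPM (log2 fold change -7.46 ± 0.25 (SE)) and spans 931 kb on chromosome 12.

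Camera called 25 of 51 fixed lists in CPT against CON, 16 higher and 9 lower; with an estimated correlation it called 0, and the lowest adjusted p was 0.0778. Of the 40 p53 target genes tested, 31 rose, 1 fell and 8 were not called, the rises including Phlda3 (58.8 ± 2.88 against 0.755 ± 0.0286 CPM), the cell cycle inhibitor gene Cdkn1a (266 ± 59.6 against 10.3 ± 2.07 CPM, log2 fold change 4.68 ± 0.18 (SE)) and Mdm2, whose product degrades p53 (log2 fold change 2.35 ± 0.11 (SE)). This list numbered 32 higher and 2 lower when adjusted over the list alone. For the p53 target genes, the median log2 fold change was 1.83 (camera adjusted p = 1.13e-11, and adjusted p = 0.0778 with an estimated correlation). Of the 28 apoptosis genes tested, 17 rose, 5 fell and 6 were not called, with the death receptor genes Tnfrsf10b (log2 fold change 3.37) and Fas (2.08) among the rises and Bax at 1.24. The apoptosis list numbered 17 higher and 5 lower when adjusted over the list alone. For the apoptosis genes, the median log2 fold change was 0.89 (camera adjusted p = 0.00605, and adjusted p = 0.259 with an estimated correlation). Of the 28 acute phase genes tested, 27 rose, 1 fell and 0 were not called, with the ferrireductase gene Steap4 at a log2 fold change of 5.03. The acute phase list numbered 27 higher and 1 lower when adjusted over the list alone. For the acute phase genes, the median log2 fold change was 3.29 (camera adjusted p = 2.02e-16, and adjusted p = 0.203 with an estimated correlation). Of the 30 IL-17 target genes fixed, 13 were tested, of which 9 rose, 1 fell and 3 were not called. The neutrophil chemokine gene Cxcl1 measured 185 ± 36.3 against 8.25 ± 3.15 CPM, and Nfkbiz had a log2 fold change of 1.95. The untested members, Il6, Tnf, Csf2 and Csf3 among them, did not pass the filter on low counts. The acute phase list also holds Lcn2 and Steap4, and the neutrophil list S100a8 and S100a9. The 13 tested targets numbered 10 higher and 1 lower when adjusted over the list alone. For the IL-17 target genes, the median log2 fold change was 2.06 (camera adjusted p = 0.000273, and adjusted p = 0.204 with an estimated correlation). Of the 20 neutrophil markers fixed, 14 were tested, of which 12 rose, 1 fell and 1 was not called. S100a8, a calcium-binding protein gene, measured 8.71 ± 3.90 against 1.05 ± 0.183 CPM. Retnlg had a log2 fold change of 5.11. Adjusted over the list alone, 12 were higher and 1 lower. Their median log2 fold change was 2.84 (camera adjusted p = 8.63e-05, and adjusted p = 0.203 with an estimated correlation). Untested Ly6g, Camp, Ngp, Mpo and Elane had at most 7 counts in a library, Stfa2l1 15.

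Of the 21 monocyte and recruited macrophage markers tested, 10 rose, 2 fell and 9 were not called, with the pore-forming protein gene Mpeg1 at 1.31 and the chemokine receptor gene Cx3cr1 at -3.81 on the log2 scale. Together they numbered 10 higher and 2 lower when adjusted over the list alone. For the monocyte and recruited macrophage markers, the median log2 fold change was 0.97 (camera adjusted p = 0.0351, and adjusted p = 0.386 with an estimated correlation). Of the 37 genes of the unfolded protein and integrated stress response tested, 24 rose, 4 fell and 9 were not called, with the endoplasmic reticulum chaperone gene Hspa5 at 409 ± 36.0 against 82.6 ± 3.90 CPM and Creld2 at a log2 fold change of 2.27. This stress list numbered 26 higher and 4 lower when adjusted over the list alone. For the genes of the unfolded protein and integrated stress response, the median log2 fold change was 1.20 (camera adjusted p = 1.73e-05, and adjusted p = 0.204 with an estimated correlation). Of the 17 immediate early genes tested, 14 rose, 3 fell and 0 were not called, with the transcription factor gene Egr1 at a log2 fold change of 4.73 and Btg2 at 6.68. Immediate early genes numbered 14 higher and 3 lower when adjusted over the list alone. For the immediate early genes, the median log2 fold change was 1.74 (camera adjusted p = 0.000336, and adjusted p = 0.203 with an estimated correlation). Of the 24 glucocorticoid receptor targets tested, 15 rose, 7 fell and 2 were not called, with the co-chaperone gene Fkbp5 at 106 ± 8.64 against 8.93 ± 1.09 CPM. Glucocorticoid receptor targets numbered 15 higher and 7 lower when adjusted over the list alone. For the glucocorticoid receptor targets, the median log2 fold change was 1.74 (camera adjusted p = 0.00590, and adjusted p = 0.309 with an estimated correlation). Of the 26 gluconeogenesis and fasting genes tested, 20 rose, 2 fell and 4 were not called, with Fbp1, a gluconeogenic phosphatase gene, at a log2 fold change of 2.83 and the urea cycle gene Cps1 at 2.21. This metabolic list numbered 20 higher and 2 lower when adjusted over the list alone. For the gluconeogenesis and fasting genes, the median log2 fold change was 1.49 (camera adjusted p = 1.46e-05, and adjusted p = 0.376 with an estimated correlation). Of the 42 genes of fatty acid oxidation and PPARA targets tested, 26 rose, 6 fell and 10 were not called, with Cpt1a, the carnitine palmitoyltransferase gene of mitochondrial import, at a log2 fold change of 1.72 and Cyp4a14 at 6.18. The oxidation list numbered 27 higher and 6 lower when adjusted over the list alone. For the genes of fatty acid oxidation and PPARA targets, the median log2 fold change was 0.62 (camera adjusted p = 0.000650, and adjusted p = 0.526 with an estimated correlation).

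Of the 53 cytosolic ribosomal protein genes tested, 46 rose, 2 fell and 5 were not called, with Rpl4 at a log2 fold change of 2.15 and Rps19 at 1.89. Ribosomal protein genes numbered 47 higher and 2 lower when adjusted over the list alone. For the cytosolic ribosomal protein genes, the median log2 fold change was 0.83 (camera adjusted p = 1.92e-12, and adjusted p = 0.203 with an estimated correlation). Of the 46 nuclear genes of oxidative phosphorylation tested, 31 rose, 3 fell and 12 were not called, with the cytochrome c oxidase subunit genes Cox7a2 at a log2 fold change of 2.03 and Cox5a at 1.99. These nuclear genes numbered 31 higher and 4 lower when adjusted over the list alone. For the nuclear genes of oxidative phosphorylation, the median log2 fold change was 0.44 (camera adjusted p = 0.000285, and adjusted p = 0.423 with an estimated correlation). Of the 15 mitochondrially encoded transcripts tested, 0 rose, 15 fell and 0 were not called, with mt-Nd4l at a log2 fold change of -2.59 and mt-Nd3 at -2.16. Mitochondrially encoded transcripts numbered 0 higher and 15 lower when adjusted over the list alone. For the mitochondrially encoded transcripts, the median log2 fold change was -1.67 (camera adjusted p = 1.46e-05, and adjusted p = 0.388 with an estimated correlation). Reads of these transcripts can also be assigned to Gm28437 and Gm28661, annotated as unprocessed pseudogenes on chromosome 1 and chosen after their values were seen, which took 6.70% ± 0.550 and 3.24% ± 0.490 of the counts in CON and 2.81% ± 0.696 and 1.51% ± 0.262 in CPT. Of the 41 genes of amino acid catabolism and the urea cycle tested, 23 rose, 10 fell and 8 were not called. The amino acid list numbered 23 higher and 10 lower when adjusted over the list alone. For the genes of amino acid catabolism and the urea cycle, the median log2 fold change was 0.42 (camera adjusted p = 0.0312, and adjusted p = 0.558 with an estimated correlation). Of the 43 complement and coagulation genes tested, 21 rose, 10 fell and 12 were not called, and without CON replicate 2 the camera adjusted p was 0.0519. With all libraries these numbered 21 higher and 11 lower when adjusted over the list alone. For the complement and coagulation genes, the median log2 fold change was 0.21 (camera adjusted p = 0.0348, and adjusted p = 0.551 with an estimated correlation). Of the 19 intestinal epithelium markers fixed, 5 were tested, of which 4 rose and 1 fell. Rises included the apolipoprotein gene Apoa4 (log2 fold change 5.03), also on the periportal hepatocyte list, and Fabp2 (1.85). Adjusted over the list alone, 4 were higher and 1 lower. Their median log2 fold change was 1.69 (camera adjusted p = 0.0276, and adjusted p = 0.207 with an estimated correlation). Sis, Lct and Muc2 were untested with 0 counts in all 9 libraries, so intestinal cells are not shown.

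Of the 22 sinusoidal endothelial markers tested, 0 rose, 20 fell and 2 were not called, with the nuclease gene Dnase1l3 at 0.605 ± 0.0467 against 19.9 ± 0.603 CPM and endoglin (Eng) at a log2 fold change of -2.73 ± 0.14 (SE). Endothelial markers numbered 0 higher and 20 lower when adjusted over the list alone. For the sinusoidal endothelial markers, the median log2 fold change was -2.45 (camera adjusted p = 6.32e-08, and adjusted p = 0.259 with an estimated correlation). Of the 21 stellate cell and fibroblast markers tested, 0 rose, 18 fell and 3 were not called, with Colec11 at 1.31 ± 0.251 against 16.1 ± 1.64 CPM. Stellate markers numbered 0 higher and 19 lower when adjusted over the list alone. For the stellate cell and fibroblast markers, the median log2 fold change was -2.35 (camera adjusted p = 1.87e-07, and adjusted p = 0.203 with an estimated correlation). Of the 31 fibrosis and extracellular matrix genes tested, 4 rose, 21 fell and 6 were not called, with the collagen gene Col1a1 at 2.02 ± 0.323 against 18.6 ± 1.74 CPM and the smooth muscle actin gene Acta2 at a log2 fold change of -3.96. Matrix genes numbered 4 higher and 21 lower when adjusted over the list alone. For the fibrosis and extracellular matrix genes, the median log2 fold change was -1.71 (camera adjusted p = 0.000455, and adjusted p = 0.386 with an estimated correlation). Of the 17 Kupffer cell markers tested, 3 rose, 10 fell and 4 were not called, with the lectin gene Clec4f at a log2 fold change of -1.37, and without CPT replicate 1 the list had camera adjusted p = 0.0818. With all libraries Kupffer markers numbered 3 higher and 10 lower when adjusted over the list alone. For the Kupffer cell markers, the median log2 fold change was -1.001 (camera adjusted p = 0.0395, and adjusted p = 0.386 with an estimated correlation). Of the 10 erythroid and megakaryocyte markers tested, 3 rose, 7 fell and 0 were not called, with the beta globin genes Hbb-bs (log2 fold change -6.53) and Hbb-bt (-7.02), which can share reads. Erythroid and megakaryocyte markers numbered 3 higher and 7 lower when adjusted over the list alone. For the erythroid and megakaryocyte markers, the median log2 fold change was -1.18 (camera adjusted p = 0.0172, and adjusted p = 0.386 with an estimated correlation).

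Of the 35 male-biased genes that depend on growth hormone tested, 1 rose, 30 fell and 4 were not called, with the fatty acid elongase gene Elovl3 at 9.77 ± 2.40 against 399.6 ± 37.4 CPM and Mup21, of the major urinary protein family whose members share reads, at a log2 fold change of -3.98. Male-biased genes numbered 1 higher and 30 lower when adjusted over the list alone. For the male-biased genes that depend on growth hormone, the median log2 fold change was -1.71 (camera adjusted p = 3.90e-10, and adjusted p = 0.204 with an estimated correlation). Of the 34 drug-metabolising cytochrome P450 genes tested, 8 rose, 20 fell and 6 were not called, with Cyp1a2 at 17.2 ± 3.09 against 704 ± 49.3 CPM and, uncertain for reads shared within their families, Cyp2c29 at a log2 fold change of -2.88 and Cyp3a11 at -2.30. P450 genes numbered 8 higher and 20 lower when adjusted over the list alone. For the drug-metabolising cytochrome P450 genes, the median log2 fold change was -0.92 (camera adjusted p = 0.00767, and adjusted p = 0.386 with an estimated correlation). Of the 23 pericentral hepatocyte genes tested, 4 rose, 14 fell and 5 were not called, while the list median was 0.05 on the TPM scale, the opposite sign, and without CPT replicate 1 the camera adjusted p was 0.0818. On the count scale this list numbered 5 higher and 14 lower when adjusted over the list alone. For the pericentral hepatocyte genes, the median log2 fold change was -0.54 (camera adjusted p = 0.0348, and adjusted p = 0.386 with an estimated correlation). The alcohol-inducible Cyp2e1 measured 3586 ± 687 against 3538 ± 471 CPM (edgeR adjusted p = 0.914). Among bile acid genes, the export pump gene Abcb11 (log2 fold change -1.63 ± 0.11 (SE)), the repressor gene Nr0b2 (-3.44 ± 0.15 (SE)) and the sterol hydroxylase gene Cyp8b1 (-1.48 ± 0.15 (SE)) fell, and the uptake carrier gene Slc10a1 (0.60 ± 0.12 (SE)) and Cyp39a1 (4.48 ± 0.21 (SE)) rose. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was not called (log2 fold change -0.14, edgeR adjusted p = 0.613), and without CPT replicate 1 it had adjusted p = 0.00910 at -0.53. Of the 16 tight junction and barrier genes tested, 6 rose, 9 fell and 1 was not called (camera adjusted p = 0.272). Their median log2 fold change was -0.60, and 0.04 on the TPM scale, the opposite sign. Among them Cldn1 (log2 fold change -2.18), Tjp3 (-2.91) and Ocln (-0.72) fell, and Tjp1 (0.39, edgeR adjusted p = 0.0207, and 0.0888 without CON replicate 2 and 0.0511 without CPT replicate 2) rose. The oxidative stress genes Hmox1 (log2 fold change 0.06, edgeR adjusted p = 0.811) and Nqo1 (1.57, adjusted p = 6.16e-06) had different outcomes, and the glutathione transferase gene Gstm3 fell (log2 fold change -3.58).

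Among the genes of the IL-17 pathway named in the study title, the receptor gene Il17ra rose in CPT (20.2 ± 3.60 against 5.78 ± 1.51 CPM, log2 fold change 1.81 ± 0.17 (SE), edgeR adjusted p = 3.32e-07), as did its partner Il17rc (16.6 ± 2.77 against 10.6 ± 0.843 CPM, adjusted p = 0.000797). Traf3ip2, the gene of ACT1, was not called (2.10 ± 0.548 against 1.29 ± 0.394 CPM, adjusted p = 0.0622), and was called without CON replicate 2 (adjusted p = 0.0287), without CPT replicate 2 (adjusted p = 0.0189) or with no filter on low counts (adjusted p = 0.0274). Traf6, the gene of a ubiquitin ligase downstream of ACT1, fell (4.71 ± 0.677 against 6.85 ± 1.5 CPM, adjusted p = 0.0176), a call lost without CON replicate 3 (adjusted p = 0.117), without CPT replicate 1 (adjusted p = 0.107) or with DESeq2 (adjusted p = 0.0535). The NF-kB subunit genes Nfkb1 (log2 fold change -0.22, adjusted p = 0.195) and Rela (0.11, adjusted p = 0.337) were not called, and the inhibitor gene Nfkbia fell (-0.38, adjusted p = 0.00364). Of the 36 receptor and adaptor genes tested, 11 rose, 11 fell and 14 were not called (camera adjusted p = 0.795). Il17a had 0 counts in all 9 libraries, below a limit of 0.105 to 0.140 CPM set by 3 counts, and Il17f had 1 count, in AT3_2, so neither ligand was detectable at this depth; floors cover counting error only. Il6 and Tnf had 0 to 2 counts in a library and were not tested. The IL-17 signaling map of the deposited annotation (55 genes) was not called in CPT against CON (camera adjusted p = 0.337). Of the 16 genes of metallothioneins and metal handling tested, 8 rose, 2 fell and 6 were not called, and the list was not called (camera adjusted p = 0.0760, and 0.00877, a call, with no filter on low counts). List medians were also taken on log2(TPM + 1), an alternative chosen after the data were seen. This scale understates changes of genes with low values, and on it the median of all tested genes was higher by 0.29 (log2) in CPT. On that scale the medians nearer to 0 by over 1.5 times were those of the lists IL-17 target genes (0.82), cytochrome P450 (-0.12), male-biased (-0.85), fibrosis and extracellular matrix (-0.15) and mitochondrially encoded transcripts (-1.02). Also nearer to 0 were Kupffer cell markers (-0.04), monocyte and recruited macrophage markers (0.41), neutrophil markers (0.67), sinusoidal endothelial markers (-0.63) and stellate cell and fibroblast markers (-0.59). Farther from 0 by over 1.5 times were amino acid catabolism and urea cycle (0.90), complement and coagulation (0.63), nuclear oxidative phosphorylation (0.92) and cytosolic ribosomal proteins (1.40). In this comparison 26 of the 51 lists were not called, among them interferon-stimulated genes, bile acid synthesis, bile acid transport, tight junctions, DNA repair, cell cycle, ferroptosis, NF-kB targets, and NRF2 targets, which had camera adjusted p = 0.0490 without CPT replicate 3.

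**Figure D1:**
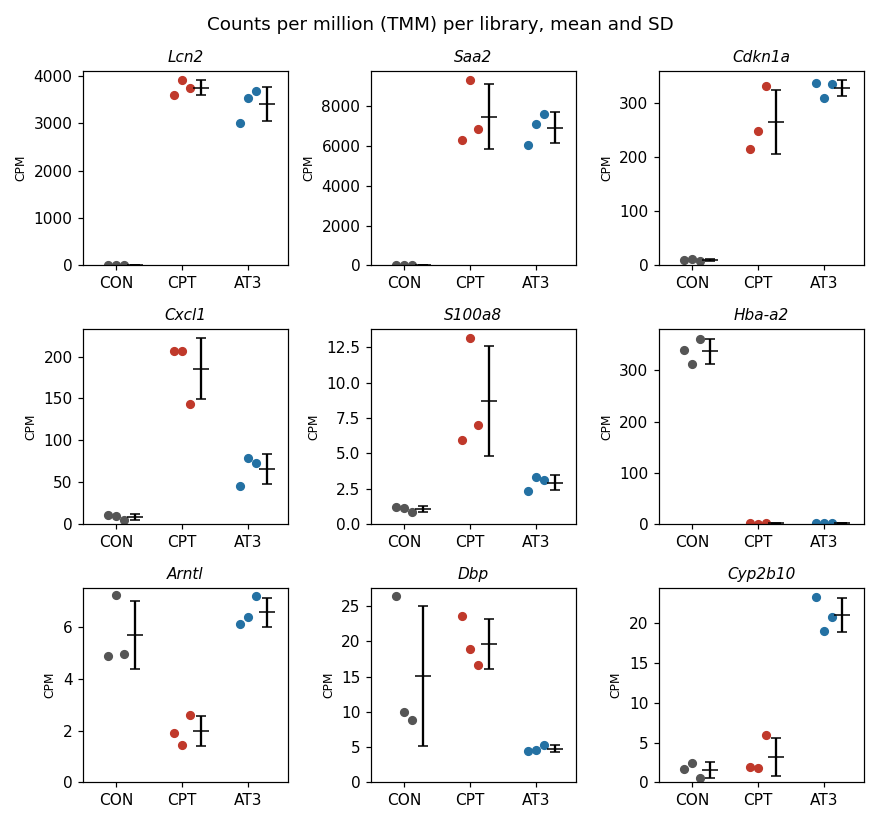
CPM (vertical axis, linear, from 0) of 9 genes in each library of CON, CPT and AT3; points are libraries, and the bar beside them is the mean with its SD (n = 3). Lcn2 measured 4.86 CPM in CON, 3752 in CPT and 3407 in AT3, and Cxcl1 measured 8.25, 185 and 65.9.

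The comparison of AT3 with CPT addresses what differs in AT3 from cisplatin injury alone. The chemokine gene Cxcl1 fell from 185 ± 36.3 to 65.9 ± 17.7 CPM (mean ± SD, n = 3 libraries a group; log2 fold change -1.49 ± 0.23 (SE), edgeR adjusted p = 0.00207), and the calprotectin genes S100a8 (2.92 ± 0.524 against 8.71 ± 3.90 CPM) and S100a9 (5.06 ± 0.254 against 15.2 ± 8.55 CPM) fell with log2 fold changes of -1.58 ± 0.25 (SE) and -1.59 ± 0.27 (SE). Cyp2b10, a cytochrome P450 gene induced through the nuclear receptor CAR, rose (21.03 ± 2.18 against 3.21 ± 2.35 CPM, log2 fold change 2.74 ± 0.34 (SE), adjusted p = 0.000665, and 3.50 without CPT replicate 3), as did the oestrogen sulfotransferase gene Sult1e1 (12.7 ± 1.25 against 3.09 ± 0.792 CPM), the elongase gene Elovl3 (36.8 ± 4.23 against 9.77 ± 2.40 CPM) and the lipoprotein lipase gene Lpl (10.8 ± 1.75 against 3.09 ± 0.557 CPM). The clock activator gene Arntl rose (6.57 ± 0.568 against 1.98 ± 0.595 CPM, log2 fold change 1.74 ± 0.21 (SE)) and the clock output gene Dbp fell (4.78 ± 0.483 against 19.7 ± 3.55 CPM, log2 fold change -2.04 ± 0.31 (SE)). The acute phase genes Lcn2 and Saa1 and the metallothionein genes Mt1 and Mt2 were not called: log2 fold changes were -0.14 ± 0.14 (SE) for Lcn2, 0.09 ± 0.14 (SE) for Saa1, -0.20 ± 0.19 (SE) for Mt1 and -0.12 ± 0.14 (SE) for Mt2 (edgeR adjusted p = 0.644, 0.787, 0.601 and 0.685). Cyp2b10 (ENSMUSG00000030483) lies on chromosome 7 from 25897620 to 25926624, Cxcl1 (ENSMUSG00000029380) on chromosome 5 from 90891241 to 90893115, Arntl (ENSMUSG00000055116) on chromosome 7 from 113207465 to 113314126 and Dbp (ENSMUSG00000059824) on chromosome 7 from 45705088 to 45710203.

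EdgeR called 641 of 13686 genes, 337 higher and 304 lower in AT3, of which 103 changed by at least 1 on the log2 scale; 2833 genes had an unadjusted p under 0.05. The 3 AT3 and 3 CPT libraries did not overlap for 27.0% of the genes, where chance gives 10%. The count depended on single libraries: it was 354 without CPT replicate 1, 229 without CPT replicate 2, 1316 without CPT replicate 3, 178 without AT3 replicate 1, 172 without AT3 replicate 2 and 228 without AT3 replicate 3. It was 1174 with no filter on low counts, 1405 with limma-voom quality weights, and 45 with limma-trend on log2(TPM + 1).

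Camera called 16 of the 51 lists between AT3 and CPT, 9 higher and 7 lower, and 0 with an estimated correlation. The lowest adjusted p was then 0.350. List medians were again taken on log2(TPM + 1). On that scale the medians nearer to 0 by over 1.5 times were those of the lists IL-17 target genes (-0.19), NF-kB feedback and target genes (-0.14), interferon-stimulated genes (-0.18), antigen presentation MHC class II (-0.25) and fibrosis and extracellular matrix (-0.08). Also nearer to 0 were stellate cell and fibroblast markers (-0.14). Farther from 0 by over 1.5 times were bile acid synthesis (0.36), conjugation and drug transport (0.23) and complement and coagulation (0.17). Of the 13 IL-17 target genes tested, 0 rose, 4 fell and 9 were not called, the falls including Cxcl1, S100a8 and S100a9, of which the neutrophil list also holds S100a8 and S100a9; of the 14 neutrophil markers, 1 rose, 3 fell and 10 were not called, with a median log2 fold change of -0.42 and camera adjusted p = 0.150. This list of targets numbered 0 higher and 5 lower when adjusted over the list alone. For the IL-17 target genes, the median log2 fold change was -0.59 (camera adjusted p = 8.94e-05, and adjusted p = 0.350 with an estimated correlation). Of the 23 NF-kB feedback and target genes tested, 0 rose, 4 fell and 19 were not called, with the adhesion molecule gene Icam1 at 21.9 ± 3.54 against 39.0 ± 3.48 CPM and the NF-kB cofactor gene Bcl3 at 15.7 ± 3.997 against 31.9 ± 3.42 CPM. NF-kB target genes numbered 1 higher and 5 lower when adjusted over the list alone. For the NF-kB feedback and target genes, the median log2 fold change was -0.34 (camera adjusted p = 0.000855, and adjusted p = 0.350 with an estimated correlation). Of the 37 interferon-stimulated genes tested, 0 rose, 7 fell and 30 were not called, with Xaf1 at a log2 fold change of -0.85 ± 0.12 (SE) and the immunoproteasome subunit gene Psmb9 at -0.70 ± 0.10 (SE). Interferon-stimulated genes numbered 0 higher and 15 lower when adjusted over the list alone. For the interferon-stimulated genes, the median log2 fold change was -0.51 (camera adjusted p = 1.36e-09, and adjusted p = 0.350 with an estimated correlation). Of the 7 MHC class II genes tested, 0 rose, 1 fell and 6 were not called, the fall being the invariant chain gene Cd74 (log2 fold change -0.65 ± 0.12 (SE)), and the list had camera adjusted p = 0.0592 without CPT replicate 3. With all libraries MHC class II genes numbered 0 higher and 3 lower when adjusted over the list alone. For the MHC class II genes, the median log2 fold change was -0.65 (camera adjusted p = 0.0315, and adjusted p = 0.502 with an estimated correlation). Of the 21 stellate cell and fibroblast markers tested, 1 rose, 3 fell and 17 were not called. Stellate cell markers numbered 1 higher and 11 lower when adjusted over the list alone. For the stellate cell and fibroblast markers, the median log2 fold change was -0.50 (camera adjusted p = 0.000196, and adjusted p = 0.350 with an estimated correlation).

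Of the 31 fibrosis and extracellular matrix genes tested, 0 rose, 0 fell and 31 were not called, and the list had camera adjusted p = 0.0705 without CPT replicate 3. With all libraries matrix genes numbered 0 higher and 0 lower when adjusted over the list alone. For the fibrosis and extracellular matrix genes, the median log2 fold change was -0.37 (camera adjusted p = 0.00119, and adjusted p = 0.502 with an estimated correlation). Of the 15 mitochondrially encoded transcripts tested, 0 rose, 4 fell and 11 were not called, with mt-Nd3 at a log2 fold change of -1.15 ± 0.19 (SE) and mt-Atp6 at -0.94 ± 0.17 (SE); their share of all counts was 13.5% in CPT and 10.3% in AT3. The mitochondrial list numbered 0 higher and 5 lower when adjusted over the list alone. For the mitochondrially encoded transcripts, the median log2 fold change was -0.37 (camera adjusted p = 0.000196, and adjusted p = 0.600 with an estimated correlation). Of the 26 gluconeogenesis and fasting genes tested, 14 rose, 0 fell and 12 were not called, with the aminotransferase gene Got1 at 666 ± 68.2 against 258 ± 109.7 CPM, the insulin receptor substrate gene Irs2 at a log2 fold change of 0.83 ± 0.14 (SE) and the transcription factor gene Foxo1 at 0.57 ± 0.10 (SE). Fasting genes numbered 19 higher and 1 lower when adjusted over the list alone. For the gluconeogenesis and fasting genes, the median log2 fold change was 0.50 (camera adjusted p = 6.64e-09, and adjusted p = 0.350 with an estimated correlation). Of the 23 periportal hepatocyte genes tested, 8 rose, 0 fell and 15 were not called. Periportal genes numbered 15 higher and 2 lower when adjusted over the list alone. For the periportal hepatocyte genes, the median log2 fold change was 0.38 (camera adjusted p = 2.24e-06, and adjusted p = 0.481 with an estimated correlation). Of the 41 genes of amino acid catabolism and the urea cycle tested, 7 rose, 0 fell and 34 were not called, with the glycine cleavage gene Gldc at 54.5 ± 2.47 against 27.4 ± 6.04 CPM. Amino acid genes numbered 14 higher and 1 lower when adjusted over the list alone. For the genes of amino acid catabolism and the urea cycle, the median log2 fold change was 0.21 (camera adjusted p = 8.94e-05, and adjusted p = 0.502 with an estimated correlation). Of the 25 cholesterol biosynthesis genes tested, 6 rose, 0 fell and 19 were not called, with the sterol sensor gene Insig1 at 45.9 ± 3.55 against 30.2 ± 1.13 CPM. Cholesterol genes numbered 8 higher and 0 lower when adjusted over the list alone. For the cholesterol biosynthesis genes, the median log2 fold change was 0.30 (camera adjusted p = 5.70e-06, and adjusted p = 0.502 with an estimated correlation).

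Of the 17 bile acid synthesis genes tested, 3 rose, 0 fell and 14 were not called, with the oxysterol hydroxylase gene Cyp39a1 at 53.4 ± 1.41 against 28.4 ± 7.20 CPM. Bile acid genes numbered 5 higher and 0 lower when adjusted over the list alone. For the bile acid synthesis genes, the median log2 fold change was 0.20 (camera adjusted p = 0.0105, and adjusted p = 0.350 with an estimated correlation). Of the 33 conjugation and drug transport genes tested, 7 rose, 3 fell and 23 were not called, with Ugt3a1 at a log2 fold change of 1.04 ± 0.13 (SE), Gstt3 at 1.05 ± 0.16 (SE) and Sult1b1 at 0.79 ± 0.10 (SE), and the list had camera adjusted p = 0.0623 without CPT replicate 1 and 0.0983 without AT3 replicate 3. With all libraries conjugation genes numbered 8 higher and 3 lower when adjusted over the list alone. For the conjugation and drug transport genes, the median log2 fold change was 0.14 (camera adjusted p = 0.0244, and adjusted p = 0.481 with an estimated correlation). Of the 20 ferroptosis and iron genes tested, 4 rose, 2 fell and 14 were not called, with the iron exporter gene Slc40a1 at a log2 fold change of 0.56 ± 0.09 (SE), and the list had camera adjusted p = 0.0932 without CPT replicate 1 and 0.0599 without CPT replicate 2. With all libraries iron genes numbered 6 higher and 2 lower when adjusted over the list alone. For the ferroptosis and iron genes, the median log2 fold change was 0.24 (camera adjusted p = 0.0315, and adjusted p = 0.350 with an estimated correlation). Of the 22 hepatocyte markers tested, 5 rose, 1 fell and 16 were not called, with the antitrypsin copies Serpina1a (log2 fold change 1.30 ± 0.19 (SE)) and Serpina1c (1.26 ± 0.14 (SE)) among the rises, which share reads and are uncertain, and the list had camera adjusted p = 0.0641 without CPT replicate 1, 0.0599 without CPT replicate 2 and 0.129 without AT3 replicate 3, while its median was 0.04 without the mitochondrially encoded and 10 most abundant genes. With all libraries hepatocyte markers numbered 8 higher and 2 lower when adjusted over the list alone. For the hepatocyte markers, the median log2 fold change was 0.12 (camera adjusted p = 0.0315, and adjusted p = 0.600 with an estimated correlation). Of the 43 complement and coagulation genes tested, 2 rose, 0 fell and 41 were not called, and the list had camera adjusted p = 0.141 without CPT replicate 1 and 0.198 without AT3 replicate 3. With all libraries complement genes numbered 3 higher and 0 lower when adjusted over the list alone. For the complement and coagulation genes, the median log2 fold change was 0.10 (camera adjusted p = 0.0244, and adjusted p = 0.661 with an estimated correlation).

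None of the p53, acute phase, apoptosis and neutrophil lists was called between AT3 and CPT (camera adjusted p = 0.199, 0.535, 0.646 and 0.150); with no filter on low counts the neutrophil list was called, with a median of -0.61 and adjusted p = 0.0218. Of the 40 p53 targets, 1 rose, 2 fell and 37 were not called; Cdkn1a had a log2 fold change of 0.31 ± 0.15 (SE) (edgeR adjusted p = 0.244, and 0.0211 without CPT replicate 3) and Mdm2 of -0.17 ± 0.10 (SE) (adjusted p = 0.357). Bax fell by 0.47 on the log2 scale (edgeR adjusted p = 0.0155), and was not called without CPT replicate 2 (adjusted p = 0.0617) or without AT3 replicates 1, 2 or 3 (adjusted p = 0.0513, 0.0953 and 0.0557). The acute phase gene Saa3 fell (123 ± 12.3 against 241 ± 26.4 CPM, adjusted p = 0.000665), and Cyp3a11 fell further (177 ± 17.5 against 402 ± 88.3 CPM, log2 fold change -1.18 ± 0.15 (SE)), with reads shared within its family. Of the 21 clock genes, 5 rose, 3 fell and 13 were not called (camera adjusted p = 0.190), with Cry1 at 14.2 ± 0.902 against 7.06 ± 0.143 CPM. Of the 37 genes of the unfolded protein and integrated stress response, 4 rose, 5 fell and 28 were not called (camera adjusted p = 0.934), with the chaperone cofactor gene Sdf2l1 at a log2 fold change of -0.60 ± 0.10 (SE) and Manf at -0.59 ± 0.10 (SE).

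In the IL-17 pathway, Traf3ip2 (2.06 ± 0.295 against 2.10 ± 0.548 CPM, edgeR adjusted p = 0.983), Traf6 (5.31 ± 0.763 against 4.71 ± 0.677 CPM, adjusted p = 0.639), Il17rc (log2 fold change -0.23 ± 0.13 (SE), adjusted p = 0.343) and Rela (log2 fold change -0.15 ± 0.10 (SE), adjusted p = 0.432) were not called between AT3 and CPT. Il17ra (14.7 ± 2.01 against 20.2 ± 3.60 CPM, adjusted p = 0.106) was not called, and was called as lower without CPT replicate 3 (adjusted p = 0.0347) or with no filter (adjusted p = 0.00852). Nfkb1 (7.46 ± 0.198 against 5.39 ± 0.642 CPM, adjusted p = 0.0647) was not called, and was called as higher without CON replicate 2 (adjusted p = 0.0439) or with no filter (adjusted p = 0.0479). Nfkbia fell by 0.40 on the log2 scale (adjusted p = 0.0331), a call lost without CPT replicate 2 (adjusted p = 0.143) or AT3 replicates 1, 2 or 3 (adjusted p = 0.139, 0.126 and 0.115). Of the 36 receptor and adaptor genes tested, 1 rose, 0 fell and 35 were not called (camera adjusted p = 0.557), and the deposited IL-17 signaling map was not called (adjusted p = 0.895). Tjp1 (log2 fold change 0.06 ± 0.13 (SE), edgeR adjusted p = 0.858) and Ocln (0.31 ± 0.14 (SE), adjusted p = 0.232), both tight junction genes, were not called. Neither Abcb11 (-0.29 ± 0.11 (SE)), Cyp8b1 (-0.07 ± 0.15 (SE)), Slc10a1 (-0.03 ± 0.12 (SE)) nor Cyp2e1 (-0.08 ± 0.14 (SE)) was called (edgeR adjusted p = 0.127, 0.852, 0.915 and 0.804). Cyp7a1 was not called either. It was called as higher with no filter (log2 fold change 0.40, edgeR adjusted p = 0.0342) or without CPT replicate 1 (0.85, adjusted p = 0.0106).

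Taking CPT against CON and AT3 against CPT together, 215 genes were called in both in opposite directions, 108 that rose in CPT and fell in AT3 and 107 that fell and then rose. Overlap of independent lists gives 91.2 and 104 genes. Moved further in the same direction were 283 genes, 159 up and 124 down, where independent lists give 101 and 93.7. Both comparisons use the CPT libraries. In 20 simulations of unchanged groups the mean count moved back was 0.05 and moved further 0. Those simulations hold no changed genes, so counts near 0 follow from their setting. They give no count to expect where CPT and CON differ as widely as here. Of the 215 genes, 98 were not called in AT3 against CON. Elovl3 (399.6 ± 37.4 CPM in CON, 9.77 ± 2.40 in CPT and 36.8 ± 4.23 in AT3) and the signalling adaptor gene Tifa (AT3 against CPT 1.05 ± 0.235 against 4.61 ± 2.06 CPM) were among the genes that moved back. The count moved back was 89 without CPT replicate 2, and 64, 68 and 77 without AT3 replicates 1, 2 and 3.

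The comparison of AT3 with CON addresses what stays different from untreated livers. The acute phase gene Lcn2 and the metallothionein gene Mt2 were higher in AT3 than in CON: Lcn2 measured 3407 ± 362 against 4.86 ± 1.39 CPM (mean ± SD, n = 3 libraries a group; log2 fold change 9.47 ± 0.21 (SE), edgeR adjusted p = 3.08e-14), and Mt2 2582 ± 143 against 1.15 ± 0.487 CPM. The list of metallothioneins and metal handling was not called (camera adjusted p = 0.0682), and was called with no filter on low counts (adjusted p = 0.00879) or without AT3 replicate 1 (adjusted p = 0.0480). The p53 targets Cdkn1a (329 ± 15.2 against 10.3 ± 2.07 CPM) and Phlda3 (log2 fold change 5.80 ± 0.14 (SE)) rose, as did Cxcl1 (65.9 ± 17.7 against 8.25 ± 3.15 CPM, log2 fold change 2.98 ± 0.26 (SE)). Dnase1l3 (1.08 ± 0.239 against 19.9 ± 0.603 CPM), Col1a1 (1.42 ± 0.378 against 18.6 ± 1.74 CPM) and Cyp1a2 (17.9 ± 4.72 against 704 ± 49.3 CPM) fell. With 0 counts in AT3, Ugt1a2, which shares exons with other Ugt1a genes and is uncertain, was at least 605-fold lower and the long gene Astn2 at least 33.0-fold lower than in CON; Cela2a, with 0 counts in CON, was at least 129-fold higher. EdgeR called 8813 of 13686 genes, 4312 higher and 4501 lower in AT3, and 4428 changed by at least 1 on the log2 scale. The libraries did not overlap for 70.3% of the genes, where chance gives 10%. On the TPM scale the median of all genes was higher by 0.32 (log2), with 7017 called higher and 1698 lower.

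Camera called 29 of the 51 lists in AT3 against CON, 18 higher and 11 lower, and 0 with an estimated correlation. The lowest adjusted p was then 0.0926. Among p53 targets, 32 of 40 rose and 1 fell, or 32 and 1 adjusted over the list alone. For the p53 targets list, camera gave adjusted p = 9.60e-11, and adjusted p = 0.0926 with an estimated correlation. Among acute phase genes, 27 of 28 rose and 1 fell, or 27 and 1 adjusted over the list alone. For the acute phase proteins list, camera gave adjusted p = 8.20e-15, and adjusted p = 0.258 with an estimated correlation. Among IL-17 targets, 9 of 13 rose and 1 fell, or 9 and 1 adjusted over the list alone. For the IL-17 target genes list, camera gave adjusted p = 0.00456, and adjusted p = 0.263 with an estimated correlation. Of 14 neutrophil markers tested, 11 rose and 1 fell, or 11 and 1 adjusted over the list alone. For the neutrophil markers list, camera gave adjusted p = 0.000459, and adjusted p = 0.258 with an estimated correlation. Among gluconeogenesis and fasting genes, 22 of 26 rose and 1 fell, or 22 and 1 adjusted over the list alone. For the gluconeogenesis and fasting response list, camera gave adjusted p = 2.41e-07, and adjusted p = 0.263 with an estimated correlation. Members included Got1 at 666 ± 68.2 against 20.5 ± 2.98 CPM. Among cholesterol biosynthesis genes, 16 of 25 rose and 5 fell, or 16 and 5 adjusted over the list alone. For the cholesterol biosynthesis list, camera gave adjusted p = 0.0241, and adjusted p = 0.582 with an estimated correlation. Members included Sqle at 24.5 ± 2.32 against 5.09 ± 1.46 CPM. Among periportal genes, 14 of 23 rose and 7 fell, or 14 and 7 adjusted over the list alone. For the periportal hepatocyte genes list, camera gave adjusted p = 0.0221, and adjusted p = 0.559 with an estimated correlation. Members included Cps1 at 2363 ± 89.0 against 346 ± 37.9 CPM.

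Among ribosomal protein genes, 45 of 53 rose and 2 fell, or 45 and 2 adjusted over the list alone. For the cytosolic ribosomal proteins list, camera gave adjusted p = 2.82e-10, and adjusted p = 0.258 with an estimated correlation. Among genes of the unfolded protein and integrated stress response, 26 of 37 rose and 3 fell, or 26 and 3 adjusted over the list alone. For the unfolded protein and integrated stress response list, camera gave adjusted p = 7.36e-06, and adjusted p = 0.258 with an estimated correlation. Among sinusoidal endothelial markers, 1 of 22 rose and 20 fell, or 1 and 20 adjusted over the list alone. For the sinusoidal endothelial markers list, camera gave adjusted p = 5.65e-07, and adjusted p = 0.263 with an estimated correlation. Among stellate cell markers, 1 of 21 rose and 19 fell, or 1 and 19 adjusted over the list alone. For the stellate cell and fibroblast markers list, camera gave adjusted p = 1.86e-07, and adjusted p = 0.219 with an estimated correlation. Among mitochondrially encoded transcripts, 0 of 15 rose and 15 fell, or 0 and 15 adjusted over the list alone. For the mitochondrially encoded transcripts list, camera gave adjusted p = 3.21e-06, and adjusted p = 0.400 with an estimated correlation. Among male-biased genes, 1 of 35 rose and 29 fell, or 1 and 29 adjusted over the list alone. For the male-biased growth hormone dependent genes list, camera gave adjusted p = 1.24e-08, and adjusted p = 0.263 with an estimated correlation. Among MHC class II genes, 0 of 7 rose and 4 fell, or 0 and 5 adjusted over the list alone. For the antigen presentation MHC class II list, camera gave adjusted p = 0.0372, and adjusted p = 0.397 with an estimated correlation. Members included Cd74 at 5.28 ± 0.488 against 36.1 ± 2.14 CPM. Among B and plasma cell markers, 1 of 9 rose and 6 fell, or 1 and 6 adjusted over the list alone. For the B and plasma cell markers list, camera gave adjusted p = 0.0440, and adjusted p = 0.303 with an estimated correlation. Members included the immunoglobulin gene Igkc at 3.85 ± 0.575 against 23.9 ± 1.36 CPM; without CON replicate 2 the camera adjusted p was 0.0634. Among interferon-stimulated genes, 5 of 37 rose and 20 fell, or 5 and 20 adjusted over the list alone. For the interferon-stimulated genes list, camera gave adjusted p = 0.0246, and adjusted p = 0.550 with an estimated correlation. Members included the GTPase gene Igtp at a log2 fold change of -1.59 ± 0.15 (SE) and Ifit1 at -2.67 ± 0.26 (SE); the list median was -0.51 on the count scale and 0.03, the opposite sign, on the TPM scale.

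Among apoptosis genes, 18 of 28 rose and 5 fell, or 18 and 5 adjusted over the list alone. For the apoptosis list, camera gave adjusted p = 0.0108, and adjusted p = 0.263 with an estimated correlation. Among glucocorticoid receptor targets, 16 of 24 rose and 7 fell, or 16 and 7 adjusted over the list alone. For the glucocorticoid receptor targets list, camera gave adjusted p = 0.00233, and adjusted p = 0.263 with an estimated correlation. Among immediate early genes, 14 of 17 rose and 2 fell, or 14 and 2 adjusted over the list alone. For the immediate early genes list, camera gave adjusted p = 0.000207, and adjusted p = 0.219 with an estimated correlation. Of 5 intestinal epithelium markers tested, 4 rose and 1 fell, or 4 and 1 adjusted over the list alone. For the intestinal epithelium markers list, camera gave adjusted p = 0.0290, and adjusted p = 0.263 with an estimated correlation. Among fatty acid oxidation and PPARA target genes, 29 of 42 rose and 6 fell, or 29 and 6 adjusted over the list alone. For the fatty acid oxidation and PPARA targets list, camera gave adjusted p = 0.000418, and adjusted p = 0.534 with an estimated correlation. Among nuclear oxidative phosphorylation genes, 29 of 46 rose and 7 fell, or 29 and 7 adjusted over the list alone. For the nuclear oxidative phosphorylation list, camera gave adjusted p = 0.000579, and adjusted p = 0.519 with an estimated correlation. Among amino acid and urea cycle genes, 27 of 41 rose and 11 fell, or 27 and 11 adjusted over the list alone. For the amino acid catabolism and urea cycle list, camera gave adjusted p = 0.00618, and adjusted p = 0.534 with an estimated correlation. Among complement and coagulation genes, 22 of 43 rose and 10 fell, or 22 and 10 adjusted over the list alone. For the complement and coagulation list, camera gave adjusted p = 0.0130, and adjusted p = 0.534 with an estimated correlation.

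Among cytochrome P450 genes, 7 of 34 rose and 20 fell, or 7 and 20 adjusted over the list alone. For the drug metabolism cytochromes P450 list, camera gave adjusted p = 0.0103, and adjusted p = 0.400 with an estimated correlation. Among pericentral genes, 4 of 23 rose and 13 fell, or 4 and 13 adjusted over the list alone. For the pericentral hepatocyte genes list, camera gave adjusted p = 0.0372, and adjusted p = 0.397 with an estimated correlation. Without CPT replicate 1 the camera adjusted p was 0.0585. Among extracellular matrix genes, 5 of 31 rose and 22 fell, or 5 and 23 adjusted over the list alone. For the fibrosis and extracellular matrix list, camera gave adjusted p = 0.000190, and adjusted p = 0.350 with an estimated correlation. Among erythroid and megakaryocyte markers, 3 of 10 rose and 7 fell, or 3 and 7 adjusted over the list alone. For the erythroid and megakaryocyte markers list, camera gave adjusted p = 0.0241, and adjusted p = 0.400 with an estimated correlation. Among hepatocyte markers, 13 of 22 rose and 6 fell, or 13 and 6 adjusted over the list alone. For the hepatocyte markers list, camera gave adjusted p = 0.0491, and adjusted p = 0.534 with an estimated correlation; the call was lost without CON replicate 1, CPT replicate 1 or AT3 replicate 3 (camera adjusted p = 0.0546, 0.0528 and 0.0560) and with DESeq2 size factors (adjusted p = 0.0506). For AT3 against CON, list medians on log2(TPM + 1) moved as well. On that scale the medians nearer to 0 by over 1.5 times were those of the lists IL-17 target genes (0.56), antigen presentation MHC class II (-1.17), cytochrome P450 (-0.01), male-biased (-0.69) and fibrosis and extracellular matrix (-0.25). Also nearer to 0 were pericentral hepatocyte genes (-0.03), neutrophil markers (0.47), B and plasma cell markers (-0.54), sinusoidal endothelial markers (-0.58) and stellate cell and fibroblast markers (-0.86). Farther from 0 by over 1.5 times were cholesterol biosynthesis (1.01), amino acid catabolism and urea cycle (1.20), complement and coagulation (0.79), nuclear oxidative phosphorylation (1.11) and cytosolic ribosomal proteins (1.43). Also farther from 0 were periportal hepatocyte genes (1.61) and hepatocyte markers (1.06). In the IL-17 pathway, Il17ra rose (14.7 ± 2.01 against 5.78 ± 1.51 CPM, edgeR adjusted p = 7.06e-06), Nfkbia fell (16.98 ± 0.131 against 29.1 ± 2.55 CPM, adjusted p = 5.65e-06), and Nfkb1 and Rela were not called (adjusted p = 0.133 and 0.783). Traf6 was not called (adjusted p = 0.0870, and 0.0305 without CON replicate 2), nor was Traf3ip2 (adjusted p = 0.0643, and 0.0283 without CON replicate 2, 0.0492 without CPT replicate 1, 0.0429 without CPT replicate 2 and 0.0284 with no filter on low counts).

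Between CPT against CON and AT3 against CON, 7450 genes were called in the same direction, 3704 up and 3746 down, and 6 in opposite directions, where independent lists give 1294 up and 1388 down. Across the tested genes, which are not independent replicates, the covariance of the log2 fold changes was 1.82, against 0.0596 in simulated unchanged groups that share the CON libraries, and the correlation was 0.950 against 0.563. With the simulated values taken away, the slope of AT3 against CON on CPT against CON was 1.05. Part of the excess in shared calls may come from the CON libraries, which with 3 cannot be divided into groups of at least 2.

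**Figure D2:**
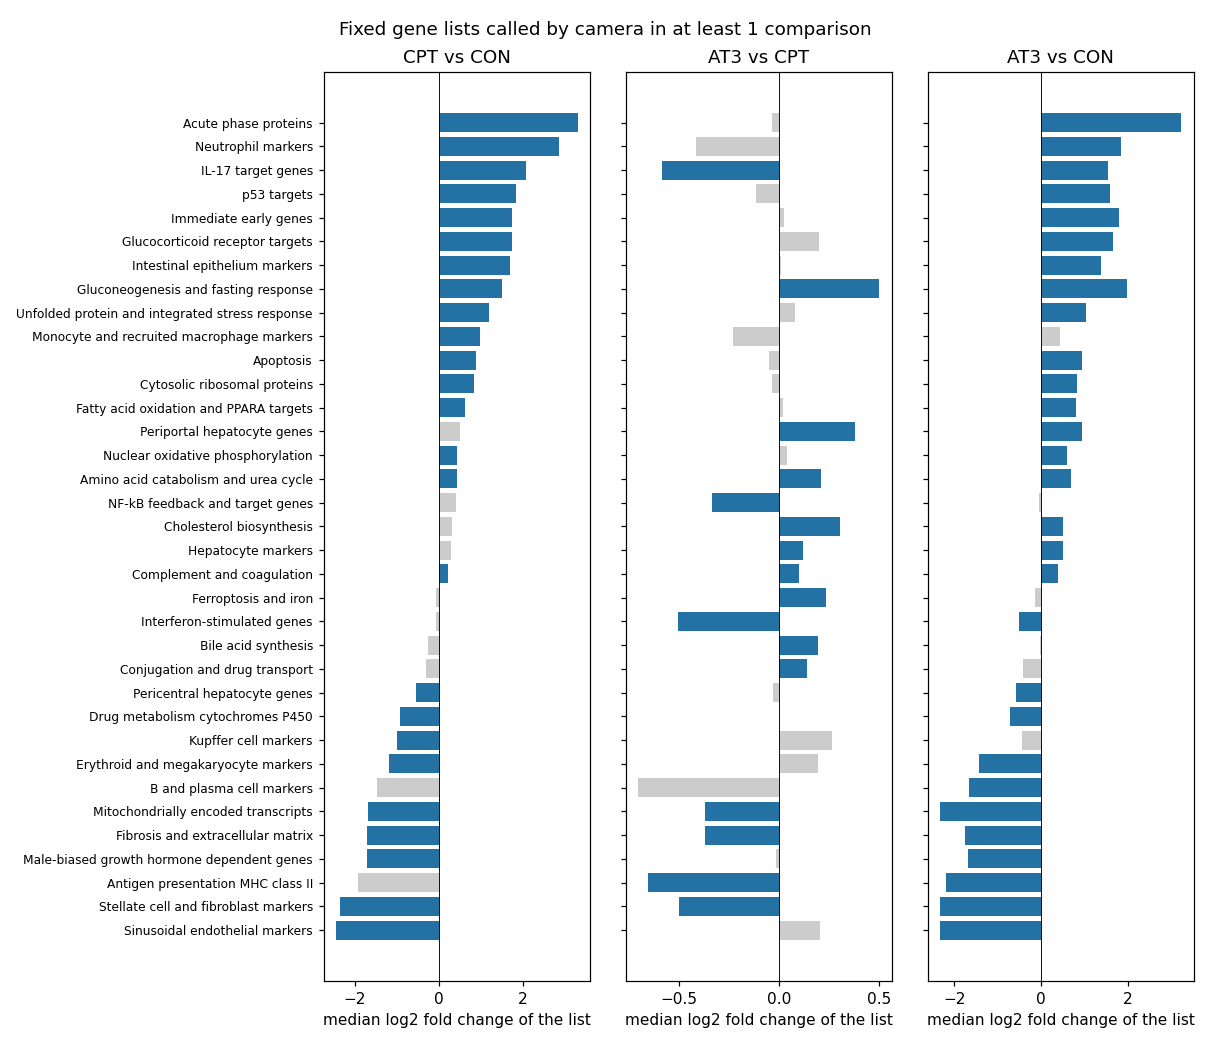
Median log2 fold change (horizontal axis, with a different range in each panel) of every fixed gene list that camera called in at least 1 of the 3 comparisons; blue bars were called and grey bars were not. The acute phase list had medians of 3.29 in CPT against CON, -0.03 in AT3 against CPT and 3.23 in AT3 against CON; the sign of the pericentral list in CPT against CON and of interferon-stimulated genes in AT3 against CON is the opposite on the TPM scale.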

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

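Alternatives for annotation terms and list medians on log2(TPM + 1) or without the most abundant genes were chosen after the data were seen; the others were fixed beforehand. On log2(TPM + 1) the medians of 2 called lists changed sign, pericentral genes in CPT against CON (0.05) and interferon-stimulated genes in AT3 against CON (0.03), and those of many lists not called did. Calls of lists, and of the part of the naming rule's genes run in alternatives, were compared for sign. None changed sign under other scaling of the counts, no filter, the block or a library left out, nor did genes under DESeq2. Signs of genes on the TPM scale were not compared. Of 236 values in that part, 193 kept their call in every alternative run on them (other scaling, no filter, DESeq2, the block and each library left out). In AT3 against CPT 32 of 94 did not. That part was drawn up for the text, whose genes were chosen after their values were seen. Its share of kept calls therefore does not stand for the rule's other genes. With no filter, AT3 against CPT had 1174 called genes, 330 moved back, the covariance was 2.498, and 196, 22 and 212 terms were called (CPT against CON, AT3 against CPT, AT3 against CON). With limma-trend on log2(TPM + 1), AT3 against CPT had 45 calls, 16 moved back and the covariance was 0.71; on log2(TPM + 0.1) these were 32, 15 and 1.29, and on log2(TPM + 1) with no filter 20, 8 and 0.45. Voom with quality weights gave 1405 and 379; a minimum log2 fold change of 1 gave 3960, 103 and 4428 genes and 36 moved back, by its construction. Camera with an estimated correlation called 0 lists and 0 terms in each comparison; fry, a test of direction within a list, called 45, 9 and 45 lists. Replicate numbers do not pair the libraries: same-number correlations of deviations from the group means were -0.0378 to 0.0762, and none of 9 exceeded 0.1. With the replicate number as a block, the genes called were 8154, 451 and 8648, 159 moved back, the covariance was 1.83 and AT3 against CPT had 1 called term. In that fit 2 list calls were lost, ferroptosis and iron in AT3 against CPT (adjusted p = 0.0511) and hepatocyte markers in AT3 against CON (0.0661). Leaving out each library in turn gave these ranges: genes 7757 to 8291, 172 to 1316 and 8253 to 9201; lists 23 to 27, 13 to 19 and 27 to 30; terms 50 to 64, 0 to 19 and 30 to 55; moved back 64 to 295; covariance 1.89 to 2.11. Apart from fewer samples when a library is left out, the cause was not tested. At this depth a 1.5-fold change was recovered in 41.8% of simulated genes in AT3 against CPT, so small differences there can be missed.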

Other observations

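The tests in this part were chosen after the result was seen, including all counts of other splits of the libraries, except the term tests, the test of length and expression on cell type markers and both tests on long genes. Among the deposited terms, camera called 61 of 1293 in CPT against CON, 31 higher and 30 lower. Higher were the ribosome map (128 genes), protein export (25 genes), protein processing in the endoplasmic reticulum (152 genes), the citrate cycle (28 genes) and p53 signaling (59 genes). Lower were sprouting angiogenesis (16 genes), Notch signaling (47 genes), focal adhesion (151 genes), collagen fibril organization (24 genes) and steroid hormone biosynthesis (62 genes). In AT3 against CPT 5 terms were called, all higher, among them the citrate cycle map (28 genes) and cysteine and methionine metabolism (47 genes); the count was 1 without CON replicate 1, 0 without CPT replicate 1, 1 without CPT replicate 2, 19 without CPT replicate 3, 3 without AT3 replicate 1 and 1 without AT3 replicate 3. With an estimated correlation 0 terms were called in each comparison.

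Markers of sinusoidal endothelial and stellate cells were lower in CPT than in CON, with a joint median log2 fold change of -2.41 over 43 genes. A higher share of hepatocyte RNA that lowered every other cell type alike would lower Kupffer cell markers as much. The 16 Kupffer cell markers had a median of -0.88, a difference of 1.52 (95% bootstrap interval over genes 0.946 to 2.23). A change in Kupffer cells would give the same difference, so this test cannot decide on the hepatocyte share. Gene length and expression level are argued against. Random lists matched on expression, transcript length and span had medians from -0.47 to 0.14 in 95% of draws. Open are a higher share of hepatocyte RNA, fewer endothelial and stellate cells, lower expression in them, and a change in Kupffer cells. Bulk RNA cannot part these. On log2(TPM + 1) the list medians were -0.63, -0.59 and -0.04 for sinusoidal endothelial, stellate and Kupffer cell markers.

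Genes with a long genomic span were lower in CPT than in CON: the median log2 fold change was 0.08 below 10 kb (4061 genes), -0.40 from 100 to 300 kb (1237 genes) and -1.28 above 300 kb (222 genes, 152 lower and 19 higher), and -1.18 above 300 kb in AT3 against CON; in AT3 against CPT the calls went the other way, with 88 higher and 165 lower below 10 kb, 102 higher and 39 lower from 30 to 100 kb, 35 higher and 8 lower from 100 to 300 kb and 11 higher and 3 lower above 300 kb. Transcript length and expression level are argued against as the whole cause, since within bins of both the Spearman correlation with span across genes was -0.0858 (-0.103 to -0.0687), although it was -0.148 without bins and that with transcript length was larger in size, -0.191. Transcripts of other cell types stay open: 666 genes above 160 kb outside the lists had a median of -0.73 where matched random lists gave -0.15 to 0.02, but the listed markers left out were only 6, too few to move that median. The Spearman correlation with span of a library's log2 CPM less the mean of the CON libraries was -0.141 to -0.157 in CPT and -0.0837 to -0.120 in AT3, while CON_2 lay at -0.0838, inside the AT3 range. Blocked elongation at platinum adducts, which long genes would meet more often, is a candidate explanation that was not tested here, and RNA quality or the share of unspliced RNA stays open.

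Between AT3 and CPT, clock genes controlled by REV-ERB and ROR (6 genes, Arntl and Cry1 among them) had a mean log2 fold change of 0.73. Those driven by CLOCK and ARNTL (9 genes, Dbp and Nr1d1 among them) had one of -0.58, a difference of 1.31. These arms were set after the changes of Arntl and Dbp, which they hold, had been seen, so the difference decides nothing; the clock list was not called (camera adjusted p = 0.190), and Ciart (0.50) went against its arm. A shift of clock phase and another time of tissue collection stay open; collection times are not given in the sources used here. Deeper fasting in AT3 stays open too: cholesterol biosynthesis genes, which fasting lowers, had a median of 0.30 (0.147 to 0.417), while gluconeogenesis and fasting genes, which it raises, had one of 0.50 (0.337 to 0.671). Nr1d1 had edgeR adjusted p = 0.0603 without AT3 replicate 1.

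Each comparison of 3 and 3 libraries has 10 splits, too few for a share under 0.05. The real splits called 8326, 641 and 8813 genes (CPT against CON, AT3 against CPT, AT3 against CON), the highest others 0, 1 and 0. Every other split mixes the groups, so their difference widens the spread and low gene counts decide nothing. For gene lists the real splits called 25, 16 and 29, each as many in 1 split, and the highest other splits 17, 15 and 21, so camera with its preset correlation also calls lists between mixed groups. For terms the real splits called 61, 5 and 43, and the highest others 11, 38 and 6; in AT3 against CPT 6 of 10 splits called at least 5 terms. The cause of the split with 38 terms was not tested.

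Of 100 splits of the 9 libraries into 3 groups of 3, 2 gave at least 215 genes moved back, the real one included. The other gave 7268 and also keeps the CON libraries together, as the middle group, while the 98 splits that part them gave 0. The outcome thus followed whether CON stayed together, and the splits say nothing on whether chance gave the 215 genes. Mirror splits, first counted more than once, were removed after that count was seen.

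Cyp2b10 had at most 2.39 CPM in a CON library, 5.92 in CPT_3 and 19.0 to 23.3 in AT3. CPT_3, with a quality weight of 0.531, lay nearer to the AT3 libraries on the principal component that parts AT3 from CPT than CPT_1 or CPT_2 did.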
